A study of Mus musculus with 6 samples.

How the data were processed

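Messenger RNA was measured by sequencing in C3H-10T1/2 cells, a mouse mesenchymal line that can be turned into fat cells in culture. There were 6 libraries, 3 from cultures given the solvent DMSO and 3 from cultures given 611 (also called Cpd A), an inhibitor of the histone demethylase LSD1, at 4 uM. All were taken after 6 days of brown adipocyte differentiation. Per the labels' protocols, induction lasted 72 h in medium with 0.5 mM isobutylmethylxanthine, 125 uM indomethacin, 1 uM dexamethasone, 20 nM insulin, 1 nM T3, 1 uM rosiglitazone and 10% serum, and was followed by medium with insulin, T3 and rosiglitazone. The labels disagree on the start of treatment: one places it at seeding and another 12 h after it, with induction 48 h later. RNA was extracted with TRIzol and libraries were made with a stranded mRNA kit, per the labels' protocols. Groups and replicate numbers were taken from the sample titles, and the series' design text calls the 3 libraries of a group biological triplicates. P-values therefore measure the spread between these 3 cultures per group and nothing wider.

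Per the submitters' processing notes, TopHat2 version 2.0.12, TopHat, SAMtools and the mouse genome build mm9 were used. The authors deposited 1 table per library with an RPKM value (reads per kilobase of transcript, relative to the library total) for each of 28430 RefSeq transcripts. The program that computed the RPKM values, its annotation release and whether it used strand are not given in the sources used here. Overlapping and antisense genes, and near-identical gene copies, therefore cannot be told apart in these values.

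Symbols were looked up by accession in a RefSeq gene table of a later assembly (GRCm38.p6), used for names only, and 27789 of the 28430 accessions matched. The 641 accessions without a symbol held 1.50% of the summed RPKM and stayed in the tests under their accession. No coordinates are printed, because the reference is of another build than mm9. Low RPKM values were whole multiples of the value of 1 read, which gave each library's total. The totals were 3.89e+07, 3.97e+07 and 3.99e+07 for DMSO replicates 1, 2 and 3 and 4.08e+07, 4.12e+07 and 4.09e+07 for 611 replicates 1, 2 and 3. Whether these are reads or read pairs is not given in the sources used here. Reads came out whole in every library, within 0.02 reads plus 2e-05 per read, for 78.2% of the 22741 transcripts above 0, 23.7% at the reference's transcript length and 54.5% at a length found by search. A search can meet a whole multiple by chance, so the recovered reads were not used in the main test. They serve as an alternative and for floors, the sharing of reads by isoforms, sampling noise and the reads of single genes. Floors are the RPKM of 3 reads and cover counting error only.

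Isoforms of 1 gene shared reads: over 2272 genes with several expressed transcripts, the isoform with the second most reads had a median of 0.971 times the reads of the first. Isoforms were therefore not summed. The transcript with the highest mean RPKM over the 6 libraries stood for its gene, which left 22942 genes.

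Before the data were examined, the design named a test for counts, and limma with trend on log2(value + 1) for the case that the tables held normalized values. RPKM values are not counts, so limma was used, with group as the only term, on log2(RPKM + 1). The planned filter needs counts, and a filter of at least 0.1 RPKM in at least 3 libraries took its place. It was chosen after the tables were seen and before any fit was run, and it left 13829 genes. P-values were adjusted by the Benjamini-Hochberg method, and an adjusted p below 0.05 was the threshold for a call. A log2 fold change is on the log2(RPKM + 1) scale, which understates the change of genes with low values. Ratios of mean RPKM are printed as folds beside it for single genes. Medians of lists are on the log2(RPKM + 1) scale unless a log2 ratio is named.

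A total of 28 gene lists with 724 entries were fixed before the data were examined, and 721 entries matched a symbol in the tables. Each list was tested with camera at a preset correlation between genes of 0.01, adjusted over the lists. Camera asks whether a list moved apart from the other genes. Camera with an estimated correlation, and fry, which asks whether a list's genes move one way on balance, were run as alternatives. Named genes were chosen by a rule fixed in advance: 22 genes given whatever their values, the 8 largest rises and the 8 largest falls, and up to 3 members of each list past the threshold in each direction. The largest changes needed a mean of at least 5 RPKM in the higher group and no overlap between the groups' libraries, and list members needed 1 RPKM. RPKM replaced a count-based unit in this rule. Genes named by the rule and not mentioned in the text are counted in their list.

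Libraries with the same replicate number deviated together from their group means. The correlations across genes of these deviations were 0.30, 0.30 and 0.18 for numbers 1, 2 and 3, and between -0.23 and -0.07 for libraries with different numbers. The numbers were therefore taken to pair the libraries, from the data and not from a statement in the labels, and a fit with the replicate number as a block was run as an alternative.

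Other alternatives were median-of-ratios scaling, TMM scaling, limma-voom on the recovered reads, no filter and a stricter one of at least 1 RPKM in all libraries of a group, a pseudocount of 0.1, another transcript per gene, an adjusted p below 0.01, a test against a fold of 1.5 and leaving out each library in turn. The test was tried on simulated data with 13829 genes, of which 200 were changed up or down and 30 others were raised 1.5-fold. Of the 200, the limma test recovered 68% of those changed 1.25-fold and 86% of those changed 1.5-fold. It recovered 100% of those changed 2-fold or 3-fold, and 5.53% of its calls were unchanged genes. Far fewer genes changed in the simulation than the 8209 called in the real data, and no pairing of libraries was simulated. These rates therefore may not carry over to the real data. The software was R 4.3.3 with limma 3.58.1, and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.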

Results

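The series compared brown adipocyte differentiation of C3H-10T1/2 cells with and without 611, an inhibitor of LSD1. LSD1, encoded by Kdm1a, removes methyl groups from histone H3 as part of complexes with CoREST proteins. The question, as the series title states it, was which genes LSD1 regulates while brown adipocytes form. The data were 6 transcriptomes at day 6, with n = 3 cultures for DMSO and n = 3 for 611 at 4 uM. Library totals lay between 3.89e+07 and 4.12e+07, and between 15732 and 16021 genes per library had a value above 0. Values are the mean RPKM ± SD over the 3 libraries of a group, unless stated otherwise. Replicates differed by more than the sampling noise of the recovered reads, with a chi-square per gene between 2.68 and 4.36 within groups over 5258 genes. All were kept as separate samples. Between groups the chi-square per gene lay between 31.2 and 42.5. The size of these values depends on whether the totals are reads or read pairs, which is not known. Correlations of log values across genes, which are not independent replicates, were between 0.996 and 0.997 within groups and between 0.972 and 0.979 across groups.

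Cells given 611 had lower levels of brown fat and general fat cell genes and higher levels of cell cycle, matrix and progenitor genes. Cox8b, a cytochrome c oxidase subunit of brown fat and muscle, fell from 28.1 ± 1.07 to 3.28 ± 0.968 RPKM, 8.56-fold lower. Cidea, a lipid droplet protein abundant in brown fat, fell from 61.7 ± 13.3 to 9.42 ± 0.840, 6.55-fold lower. In the other direction, Spp1, the secreted matrix protein osteopontin, rose 7.85-fold from 5.04 ± 0.421 to 39.6 ± 0.0856, and Ccnd1, the cell cycle regulator cyclin D1, rose 4.49-fold from 5.99 ± 0.288 to 26.9 ± 0.796. Of 13829 genes tested, 5758 were higher and 2451 lower with 611 (limma, Benjamini-Hochberg adjusted p below 0.05), so 70.1% of the calls were higher. After median-of-ratios scaling 3948 were higher and 3959 lower, 49.9% higher. That scaling moved the median log2 fold change of all genes from 0.10 to 0.00, a shift of 0.11. The scaling lowers every 611 library, so the 2451 genes lower without it could only go further down. Of the 5758 genes higher without it, 3948 remained higher after it. Changes of at least 1 on the log2 scale numbered 496 higher and 88 lower, and 312 higher and 138 lower after scaling.

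**Figure D1:**
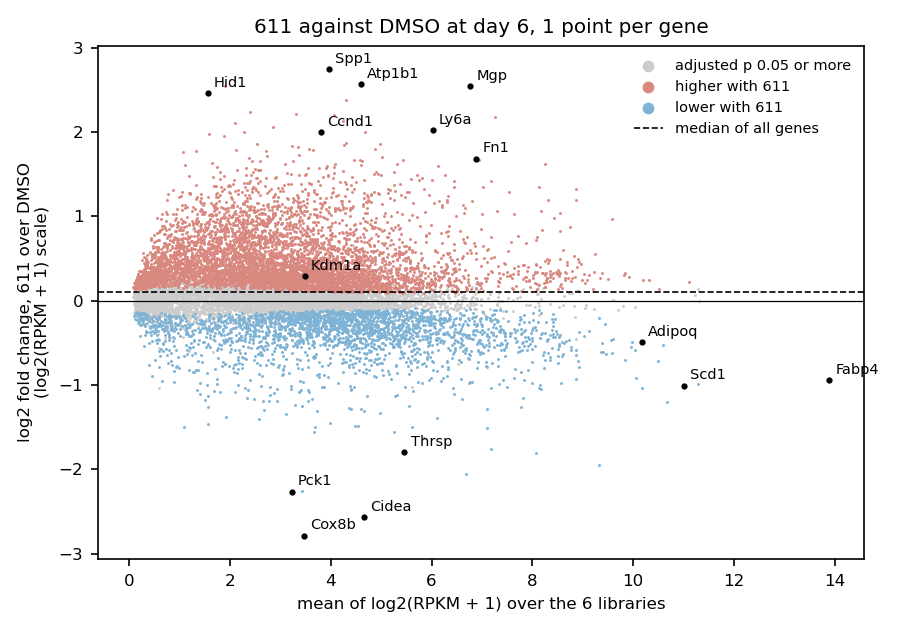
Each point is 1 of the 13829 genes tested, with the mean of log2(RPKM + 1) over the 6 libraries on the horizontal axis and the log2 fold change of 611 over DMSO on the vertical axis. The 5758 genes higher with 611 are red, the 2451 lower are blue, and the dashed line is the median of all genes at 0.10. Of the genes marked in black, Cox8b at -2.79 and Cidea at -2.57 lie lowest and Spp1 at 2.75 and Atp1b1 at 2.57 highest.

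The 8 largest falls under the naming rule were those of Cox8b, Cidea, Pck1, Sptlc3, Ces1d, Ifi27l2a, Acaa1b and Thrsp. Pck1, the phosphoenolpyruvate carboxykinase that feeds glyceride synthesis in fat cells, went from 19.6 ± 1.78 to 3.28 ± 0.458 RPKM, 5.96-fold lower. Sptlc3, a serine palmitoyltransferase subunit of sphingolipid synthesis, was 5.73-fold lower at 3.94 ± 0.770 against 22.6 ± 3.45. Ces1d, a carboxylesterase that acts on triglycerides, was 4.18-fold lower at 49.7 ± 8.45 against 208 ± 14.5. Ifi27l2a, an interferon-inducible gene, was 3.77-fold lower at 336 ± 97.2 against 1267 ± 185. Acaa1b, a peroxisomal thiolase, and Thrsp, a gene tied to fatty acid synthesis, were 3.52-fold and 3.54-fold lower. The 8 largest rises were those of Spp1, Atp1b1, Mgp, Renbp, Hid1, Aqp1, Atp6v0e2 and Itgbl1. Mgp, the matrix Gla protein that inhibits calcification, rose 5.95-fold from 44.2 ± 2.90 to 263 ± 5.75. Atp1b1, a beta subunit of the sodium pump, rose 6.46-fold to 58.4 ± 8.95, and the water channel gene Aqp1 rose 5.74-fold to 44.5 ± 6.40. Hid1 rose from 0.256 ± 0.0544 to 5.91 ± 0.577, 23.1-fold, and Renbp from 0.557 ± 0.227 to 8.05 ± 0.515, 14.5-fold. All 16 genes kept the 3 libraries of one group above the 3 of the other, as the rule required, and their limma adjusted p-values (Benjamini-Hochberg) ran from 4.4e-08 for Spp1 to 3.5e-05 for Ifi27l2a.

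Kdm1a itself, the gene of the inhibited enzyme, was slightly higher with 611, at 11.3 ± 0.331 RPKM against 9.09 ± 0.331 (1.248-fold, limma Benjamini-Hochberg adjusted p = 7.4e-04). Median-of-ratios scaling moved its log2 fold change from 0.29 to 0.15 (limma Benjamini-Hochberg adjusted p = 0.0174). An inhibitor acts on the protein, so the transcript does not check the labels. Of 19 tested members of the list of LSD1 and its complex partners, 16 were higher and 0 lower, and the counts adjusted over the list alone were the same 16 and 0. Phf21a, a reader of unmethylated histone H3 in the CoREST complex, was 1.48-fold higher at 5.16 ± 0.343, Gse1 was 1.40-fold higher at 7.69 ± 0.432, and the CoREST gene Rcor1 was 1.33-fold higher at 9.30 ± 0.326. Scaling moved their log2 fold changes from 0.46 to 0.34, from 0.42 to 0.29 and from 0.36 to 0.23. The list moved apart from other genes (camera adjusted p = 0.0267, median log2 fold change 0.28). After median-of-ratios scaling 7 members were higher, the median was 0.14 and the adjusted p was 0.105, and with an estimated correlation the adjusted p was 0.525. Over all camera alternatives it ran from 0.00992 to 0.525. Removing the trend on transcript length, GC content and expression level over all genes moved the list's median from 0.28 to 0.06. The median of its 16 higher members moved from 0.29 to 0.12. Much of the rise of this list therefore went with that trend.

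Brown fat genes were lower as a group, with exceptions. In the brown thermogenic list 16 of 27 tested members fell and 2 rose, with a median log2 fold change of -0.28, and adjusted over the list alone 17 fell and 3 rose (camera adjusted p = 1.6e-07; adjusted p = 0.298 with an estimated correlation). The median log2 ratio of mean RPKM, without the added 1, was -0.71 for this list and -0.76 for the general adipocyte list. Beside Cox8b and Cidea, the oxidase subunit gene Cox7a1 fell 2.69-fold, from 8.60 ± 1.24 to 3.20 ± 0.338. Elovl3, a fatty acid elongase of brown fat, fell 1.98-fold from 151 ± 9.42 to 76.0 ± 7.85. Prdm16, a transcriptional regulator of brown fat identity, was low in both groups and fell from 0.338 ± 0.0193 to 0.104 ± 0.0534 (limma Benjamini-Hochberg adjusted p = 0.00298). Elovl6, another elongase, rose 2.27-fold, from 6.63 ± 0.181 to 15.05 ± 1.503. Ppargc1a, a coactivator of mitochondrial genes, was at 0.527 ± 0.0999 with DMSO and 0.705 ± 0.157 with 611, which did not pass the test (limma Benjamini-Hochberg adjusted p = 0.129). Ucp1, the uncoupling protein of brown fat, was listed at 0 in all 6 libraries. A value of 3 reads would be between 0.0445 and 0.0472 RPKM for Ucp1. Both groups lay below that floor, so Ucp1 was not seen in the DMSO cells either. By counting error alone, only a difference below the floor could have been missed. How reads were assigned to Ucp1 is not known, so a loss at that step could have hidden a larger difference. Dio2, the deiodinase that activates thyroid hormone, was at 0.0231 ± 0.0131 with DMSO and between 0.00835 and 0.00843 in the libraries with 611, too low to test.

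General adipocyte genes were lower as well. Of 39 tested members of their list 36 fell and 2 rose, with a median log2 fold change of -0.70, and adjusted over the list alone 37 fell and 2 rose (camera adjusted p = 2.7e-21; adjusted p = 0.298 with an estimated correlation). Pparg and Cebpa, the transcription factors that drive fat cell formation, fell 1.39-fold from 62.8 ± 1.09 to 45.2 ± 1.19 and 1.17-fold from 68.2 ± 2.73 to 58.2 ± 4.93. Fabp4, the fatty acid binding protein with the highest value of the named genes, fell 1.92-fold from 21052 ± 790.3 to 10946 ± 573, a call that ended when no filter on low values was used (limma Benjamini-Hochberg adjusted p = 0.0549, and 6.0e-09 to 8.4e-04 in the other alternatives). The hormone gene Adipoq fell 1.40-fold from 1366 ± 8.60 to 975 ± 70.1, and the lipid droplet gene Plin1 fell 1.58-fold from 457 ± 16.5 to 289.9 ± 24.6. Cfd, the secreted protease adipsin, fell 3.13-fold from 101 ± 11.9 to 32.3 ± 6.11. Cebpd, a factor of early fat cell formation, and Sncg rose 1.599-fold and 1.62-fold. In the same libraries 11 of 16 progenitor markers were higher.

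Lipid synthesis and mitochondrial genes were lower too. For fatty acid and triglyceride synthesis 17 of 22 members fell and 2 rose, both over all genes and adjusted over the list alone (median log2 fold change -0.34, camera adjusted p = 2.7e-08; adjusted p = 0.298 with an estimated correlation). The desaturase gene Scd1 fell 2.01-fold from 2929.9 ± 149 to 1459.8 ± 117 RPKM, the citrate carrier gene Slc25a1 fell 1.76-fold to 180.3 ± 15.2 and Gpam, which starts glycerolipid synthesis, fell 1.67-fold to 39.96 ± 1.39. Mitochondrial fatty acid oxidation had 20 of 22 members lower and 2 higher, again the same adjusted over the list alone, with a median of -0.50 (camera adjusted p = 8.2e-12; adjusted p = 0.298 with an estimated correlation). Hadhb, of the trifunctional protein, fell 1.97-fold from 536 ± 11.5 to 271 ± 12.8 and the dehydrogenase gene Acadm 1.73-fold from 636 ± 30.3 to 367 ± 16.9. Cpt1a, which admits fatty acids to mitochondria, rose 1.57-fold to 29.5 ± 1.06. In the tricarboxylic acid cycle 18 of 19 members fell and 1 rose, also adjusted over the list alone (median -0.51, camera adjusted p = 8.2e-12; adjusted p = 0.298 with an estimated correlation), among them Mdh1, a cytosolic enzyme of the list, 1.67-fold lower at 281 ± 10.8 against 469 ± 6.68. The 1 higher member, Idh2, lost its call after median-of-ratios scaling.

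The respiratory chain moved almost as a block by a small amount. Of 75 nuclear genes for its subunits and the ATP synthase, 73 fell and 0 rose, and adjusted over the list alone the counts were 73 and 0 (median log2 fold change -0.39, camera adjusted p = 2.5e-30; adjusted p = 0.298 with an estimated correlation). Uqcrq of complex III fell 1.55-fold from 487 ± 21.2 to 314 ± 18.5, Ndufs3 of complex I fell 1.54-fold from 161 ± 6.68 to 104 ± 5.49 and Ndufa3 fell 1.53-fold from 155 ± 0.734 to 101 ± 5.01. After median-of-ratios scaling 74 of the 75 fell and the median was -0.54.

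Cell cycle genes rose together. Of 37 tested members 36 were higher with 611 and 0 lower, over all genes and adjusted over the list alone, with a median log2 fold change of 1.07 (camera adjusted p = 3.2e-13; adjusted p = 0.298 with an estimated correlation). Top2a, the topoisomerase of dividing cells, rose 2.51-fold from 18.8 ± 0.706 to 47.2 ± 4.199. Prc1, which organises the spindle midzone, rose 2.59-fold from 9.61 ± 0.558 to 24.9 ± 1.91, and Ect2, needed for cytokinesis, rose 3.02-fold from 2.21 ± 0.0991 to 6.66 ± 0.382. After median-of-ratios scaling 35 remained called higher and 0 lower, with a median of 0.93.

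Matrix, progenitor and contractile genes were higher as well. In the collagen and matrix list 26 of 33 tested members rose and 3 fell, the same adjusted over the list alone (median log2 fold change 1.00, camera adjusted p = 8.5e-06; adjusted p = 0.298 with an estimated correlation). Fn1, fibronectin, rose 3.25-fold from 64.9 ± 3.47 to 211 ± 6.49 and the elastic fibre gene Fbln5 rose 4.83-fold from 8.004 ± 0.204 to 38.7 ± 3.25, while Thbs1, thrombospondin, fell 1.71-fold to 7.20 ± 0.180. Of 16 progenitor markers 11 rose and 1 fell, also adjusted over the list alone (median 0.75, camera adjusted p = 0.0107; adjusted p = 0.437 with an estimated correlation). The surface marker gene Ly6a rose 4.15-fold from 31.3 ± 2.77 to 130.0 ± 2.88, the receptor gene Pdgfrb rose 2.53-fold from 17.7 ± 0.911 to 44.7 ± 0.745 and Vcam1 rose 2.69-fold, while Zfp423, a factor that commits cells to the fat lineage, fell 1.30-fold to 3.12 ± 0.290. Among 17 myofibroblast and smooth muscle genes 12 rose and 1 fell, over all genes and adjusted over the list alone (median 0.79, camera adjusted p = 0.0119; adjusted p = 0.298 with an estimated correlation). Acta2, smooth muscle actin, rose 2.55-fold from 22.1 ± 0.836 to 56.4 ± 3.75 and the actin-binding gene Cald1 rose 2.66-fold to 60.7 ± 4.10. In the same libraries 36 of 39 general adipocyte genes were lower.

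**Figure D2:**
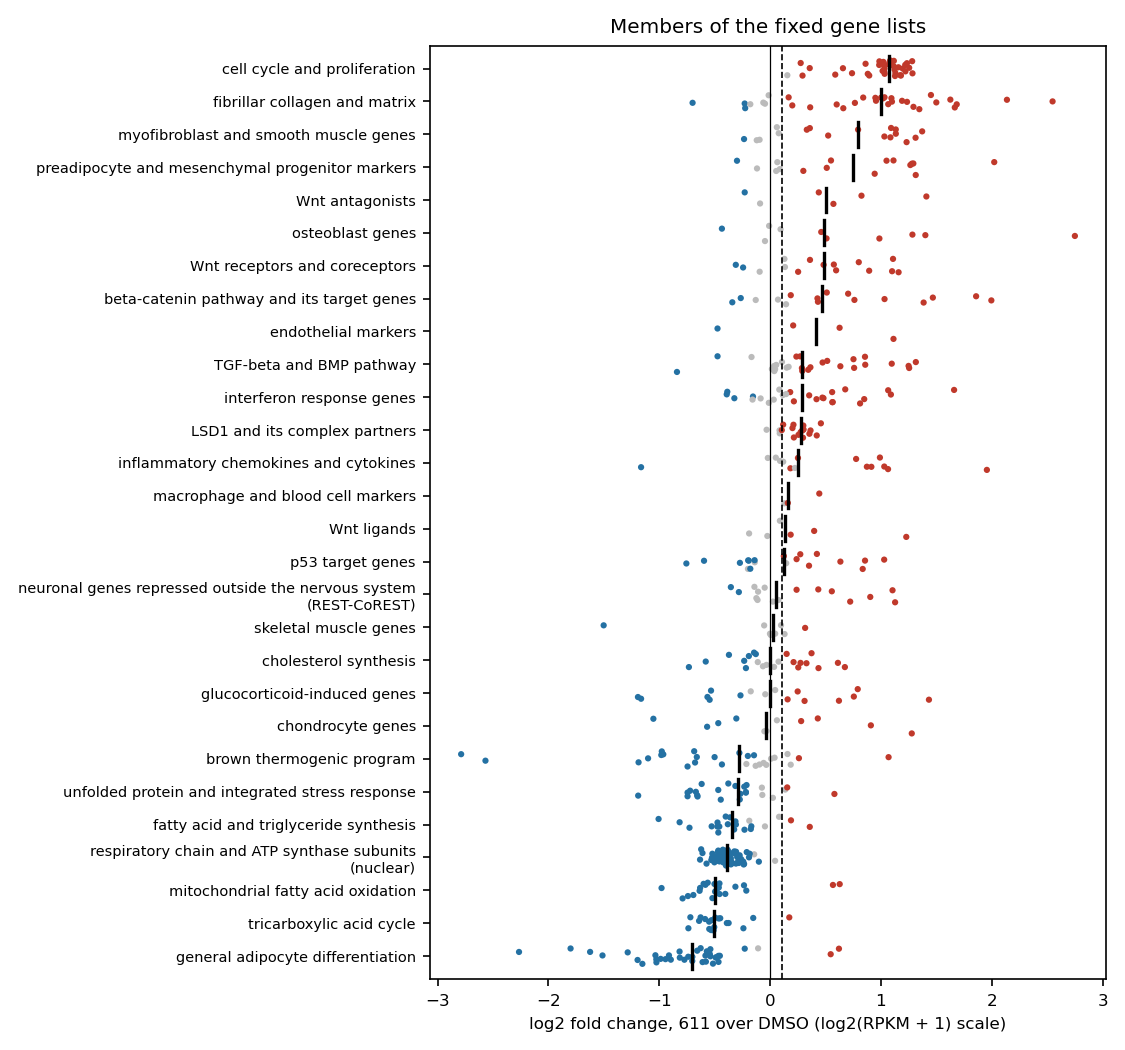
Each point is a tested member of 1 of the 28 gene lists, placed by its log2 fold change of 611 over DMSO on the log2(RPKM + 1) scale, with members higher at adjusted p below 0.05 in red, lower in blue and others in grey. Black bars are list medians and the dashed line is the median of all genes at 0.10. Cell cycle genes, with a median of 1.07, and general adipocyte genes, with a median of -0.70, lie at opposite ends, as they do after median-of-ratios scaling at 0.93 and -0.85.

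After median-of-ratios scaling, which sets the median of all genes to 0, the lists called lower had medians of -0.35 (brown thermogenic), -0.85 (general adipocyte), -0.49 (fatty acid and triglyceride synthesis), -0.54 (respiratory chain), -0.65 (fatty acid oxidation), -0.66 (tricarboxylic acid cycle) and -0.42 (stress response). The lists called higher had medians of 0.93 (cell cycle), 0.87 (collagen and matrix), 0.68 (progenitor), 0.66 (myofibroblast), 0.37 (osteoblast), 0.34 (Wnt receptors), 0.33 (beta-catenin), 0.17 (TGF-beta and BMP) and 0.20 (inflammatory). The LSD1 list, with a median of 0.14, lost its camera call there (adjusted p = 0.105). These medians are on the log2(RPKM + 1) scale, which understates the change of lists with many low values. With an estimated correlation and no scaling, camera called none of the lists in this paragraph.

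Wnt signalling restrains fat cell formation, and its genes gave a mixed picture. Of 19 Wnt ligand genes 6 could be tested, of which 3 rose and 0 fell, also adjusted over the list alone, and the list did not move apart from other genes (camera adjusted p = 0.760, median log2 fold change 0.14). Wnt5b rose 4.44-fold from 0.669 ± 0.0810 to 2.97 ± 0.846 RPKM and Wnt9a 1.75-fold from 0.759 ± 0.0624 to 1.33 ± 0.267. Wnt5a, at 3.27 ± 0.388 and 3.55 ± 0.592, and Wnt10b, at 0.125 ± 0.0243 and 0.106 ± 0.0231, did not pass the test (limma Benjamini-Hochberg adjusted p = 0.497 and 0.706). Wnt1, Wnt6 and Wnt10a were too low to test. Wnt10a was listed at 0 in all 6 libraries, Wnt1 had a value above 0 only in 611 replicate 2, at 0.0205, and Wnt6 was at 0.0979 ± 0.0206 with DMSO and 0.0473 ± 0.0355 with 611.

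Wnt receptors and coreceptors had 10 of 15 members higher and 2 lower, the same adjusted over the list alone (median log2 fold change 0.48, camera adjusted p = 0.0378; adjusted p = 0.521 with an estimated correlation and 0.0593 with a stricter filter, from 0.0135 to 0.521 over all camera alternatives). Fzd2 rose 2.38-fold to 19.6 ± 1.21, Ror1 rose 3.11-fold to 3.75 ± 0.404 and Lgr4, a receptor of R-spondins, rose 2.24-fold to 27.8 ± 2.22, while Fzd5 fell 1.35-fold to 2.10 ± 0.174. In the list of the beta-catenin pathway and its targets 11 of 16 members rose and 2 fell, also adjusted over the list alone (median 0.47, camera adjusted p = 0.0238; adjusted p = 0.401 with an estimated correlation). Its largest rises were those of Ccnd1 and of the R-spondin genes Rspo2, 3.77-fold from 15.6 ± 2.40 to 58.7 ± 2.71, and Rspo3, 3.28-fold from 3.54 ± 0.304 to 11.6 ± 1.47. R-spondins strengthen Wnt signals from outside the cell. Axin2, a direct target often read as a measure of the pathway, was at 0.153 ± 0.0586 and 0.210 ± 0.0121 and did not pass the test (limma Benjamini-Hochberg adjusted p = 0.323). Lef1, a factor of the pathway, was at 0.595 ± 0.0654 and 0.457 ± 0.0196 (limma Benjamini-Hochberg adjusted p = 0.0794), and was called lower after median-of-ratios scaling (adjusted p = 0.0246, with 0.0246 to 0.233 over all alternatives). Myc fell 1.22-fold to 11.0 ± 0.915. Of 6 Wnt antagonist genes 4 rose and 1 fell, the same adjusted over the list alone (camera adjusted p = 0.517, median 0.51), with Kremen1 1.89-fold higher at 11.8 ± 0.0506.

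**Figure D3:**
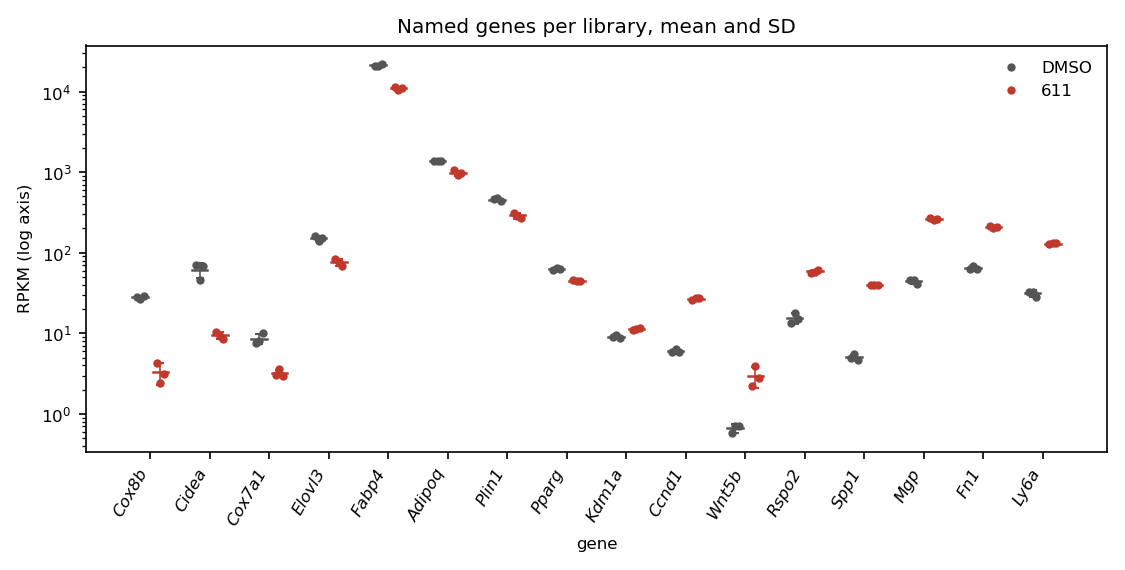
Points are the 3 libraries of each group for 16 named genes along the horizontal axis, on a vertical log axis of RPKM, DMSO in grey and 611 in red, with bars for the mean and the SD. Cidea falls from 61.7 to 9.42 and Spp1 rises from 5.04 to 39.6, and for the genes shown the points of the groups do not overlap.

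Among signalling and stress genes, the TGF-beta and BMP list had 17 of 28 tested members higher and 2 lower, and 18 and 2 adjusted over the list alone (median log2 fold change 0.29, camera adjusted p = 0.0381; adjusted p = 0.390 with an estimated correlation and 0.0685 with a stricter filter, from 0.0162 to 0.390 over all camera alternatives). Removing the trend on transcript length, GC content and expression level moved the median of this list from 0.29 to 0.11. Tgfb3 rose 3.16-fold to 6.95 ± 0.219 and the receptor gene Tgfbr2 rose 2.43-fold from 26.4 ± 1.01 to 64.3 ± 4.23. Inflammatory chemokines and cytokines had 9 of 15 higher and 1 lower, and 10 and 1 adjusted over the list alone (median 0.25, camera adjusted p = 0.0408; adjusted p = 0.318 with an estimated correlation). With the replicate block the adjusted p of this list was 0.0515, and it was 0.0559 without DMSO replicate 3, 0.0534 without 611 replicate 1 and 0.0533 without 611 replicate 2, and over all camera alternatives it ran from 0.00770 to 0.318. The inflammatory list had a median log2 ratio of mean RPKM, without the added 1, of 1.04. Ccl2, a monocyte attractant, rose 7.18-fold from 0.880 ± 0.0520 to 6.32 ± 0.778. Cxcl12 rose 2.05-fold from 138 ± 0.913 to 283 ± 16.1, while Lcn2 fell 2.42-fold to 7.26 ± 0.758. In the unfolded protein and integrated stress response list 18 of 24 members fell and 2 rose, the same adjusted over the list alone (median -0.29, camera adjusted p = 1.6e-07; adjusted p = 0.377 with an estimated correlation). Trib3 fell 2.60-fold from 10.8 ± 2.53 to 4.15 ± 1.07 and the hormone gene Fgf21 fell 2.02-fold to 1.92 ± 0.417, while Phgdh, the first enzyme of serine synthesis, rose 1.504-fold to 59.4 ± 5.01.

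The other lists did not move apart from the rest of the genes, though single members changed. Osteoblast genes had 6 of 10 higher and 1 lower (camera adjusted p = 0.182, median log2 fold change 0.49), a list that was called higher after median-of-ratios scaling (adjusted p = 0.0466, from 0.00749 to 0.556 over all camera alternatives). Beside Spp1, Tnfrsf11b, the decoy receptor osteoprotegerin, rose 3.14-fold to 6.37 ± 0.338, and Alpl, alkaline phosphatase, fell 2.06-fold to 0.498 ± 0.0859. Interferon response genes had 15 of 26 higher and 4 lower (camera adjusted p = 0.265, median 0.28), with Bst2 4.09-fold higher at 9.88 ± 1.83. Cholesterol synthesis had 9 of 22 higher and 8 lower (camera adjusted p = 0.337, median 0.00), and 6 higher and 11 lower after median-of-ratios scaling, with a median of -0.15. Its transcription factor gene Srebf2 rose 1.62-fold to 46.5 ± 2.27 and Insig1 fell 1.496-fold to 356 ± 18.1. Glucocorticoid-induced genes had 7 of 16 higher and 6 lower (camera adjusted p = 0.279, median 0.00), and 4 higher and 7 lower after that scaling, with a median of -0.15. The metallothionein gene Mt2 rose 2.76-fold to 88.0 ± 9.73 and the phosphatase gene Dusp1 fell 2.48-fold to 6.76 ± 0.322. For p53 targets 9 of 19 were higher and 7 lower (camera adjusted p = 0.514, median 0.12), and 7 higher and 8 lower after scaling, where the sign of the median turned to -0.03. Cdkn1a, an inhibitor of the cell cycle, fell 1.52-fold from 149 ± 5.21 to 98.1 ± 1.37. Chondrocyte genes had 4 of 11 higher and 4 lower (camera adjusted p = 0.446, median -0.03), with Col2a1 3.35-fold higher at 5.22 ± 0.590 and Prg4 2.33-fold lower at 4.33 ± 0.0987.

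Neuronal genes that REST and CoREST complexes repress outside the nervous system could be tested for 16 of 35 members, of which 7 were higher and 2 lower (camera adjusted p = 0.908, median log2 fold change 0.05). The median log2 ratio of mean RPKM of these members, without the added 1, was 0.52. After median-of-ratios scaling 7 were higher and 6 lower. Dnm1, a dynamin of synaptic vesicle uptake, rose 2.79-fold from 1.98 ± 0.0396 to 5.53 ± 0.379 and the growth factor gene Bdnf rose 2.84-fold from 1.67 ± 0.174 to 4.75 ± 0.405. Of 8 skeletal muscle genes tested 1 rose and 1 fell (camera adjusted p = 0.495, median 0.03, -0.02 after scaling), and the one that fell was the actin gene Acta1, from 2.63 ± 0.548 to 0.273 ± 0.0790, 9.63-fold. Markers of other cell types were few. In the macrophage and blood cell list 3 of 16 members reached the filter, 2 of them higher (camera adjusted p = 0.495, median 0.16), and Cd14 was the highest at 1.63 ± 0.517 with 611. Endothelial markers reached it for 4 of 14, with 3 higher and 1 lower (camera adjusted p = 0.495, median 0.42); Eng, which mesenchymal cells also express, rose 3.12-fold to 3.78 ± 0.157 and Egfl7 fell 1.44-fold to 7.49 ± 0.555. Adjusted over the list alone, the counts were the same for the osteoblast, glucocorticoid, p53, chondrocyte, neuronal, skeletal muscle and endothelial lists, 16 higher and 4 lower for interferon genes, 9 and 9 for cholesterol synthesis, and 3 and 0 for macrophage markers.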

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

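Median-of-ratios scaling of the RPKM values, leaving out each library, the replicate block, the filters, the pseudocount for the counts of genes, camera with an estimated correlation and fry were planned before the data were examined, while TMM scaling, limma-voom for the lists, the pseudocount for lists and named genes and the other choice of transcript were chosen after they were seen. Planned count-based fits were not run, because the tables hold RPKM and not counts, and their scalings and fold test were replaced by forms that fit RPKM. The count of lower genes was 2451, and it was 3959 after median-of-ratios scaling, 3902 after TMM scaling and 3924 with limma-voom on the recovered reads. The 611 libraries were scaled down by 1.11-fold against DMSO in the first of these, which moved the median of all genes by 0.11, so the change of the split follows from the scaling itself. Against a fold of at least 1.5, 796 genes were higher and 160 lower, a stricter test by construction. Leaving out a library gave between 5171 and 5533 higher and between 2165 and 2327 lower genes, with 1 library fewer.

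With the replicate block 6169 genes were higher and 2700 lower. It ended 1 call given here, that of the inflammatory list (adjusted p = 0.0515), and changed no other call of a list or named gene. Leaving out a library gave that list an adjusted p between 0.0236 and 0.0559, above the threshold without DMSO replicate 3, 611 replicate 1 or 611 replicate 2, and the cause was not tested beyond the smaller number of libraries.

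With an estimated correlation camera ended all 16 list calls. The adjusted p was 0.298 for the brown thermogenic, general adipocyte, fatty acid synthesis, respiratory chain, fatty acid oxidation, tricarboxylic acid cycle, matrix, myofibroblast and cell cycle lists, 0.437 for progenitor markers, 0.521 for Wnt receptors, 0.401 for the beta-catenin list, 0.525 for LSD1 partners, 0.318 for inflammatory genes, 0.390 for TGF-beta and 0.377 for the stress response. The cause was not tested. Each of these was the highest adjusted p of its list over all camera alternatives, and the lowest ran from 1.7e-32 (respiratory chain) to 0.0162 (TGF-beta). The LSD1 list had an adjusted p of 0.105 after median-of-ratios scaling, 0.0977 after TMM scaling and 0.103 with limma-voom. A stricter filter gave 0.0593 for Wnt receptors and 0.0685 for TGF-beta, and the cause was not tested. The osteoblast list passed the threshold at 0.0466 with median-of-ratios scaling, 0.0493 with TMM scaling, 0.0434 with limma-voom, 0.00749 with the stricter filter and 1.1e-04 with fry, and the cause was not tested.

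Fry, which does not compare a list with other genes, gave adjusted p-values of 0.0136 for Wnt ligands, 0.0144 for Wnt antagonists, 0.00439 for interferon genes and for macrophage markers, and 1.1e-04 for neuronal and endothelial genes. It gave the direction up for chondrocyte genes (0.0138) and p53 targets (0.0145), where camera gave down with and without median-of-ratios scaling. Their mean unscaled log2 fold changes were 0.04 and 0.12. Camera compares a list with the other genes and fry does not, so the directions need not be the same. The cause was not tested further. Of the 139 named genes none changed direction past the threshold in these settings; calls ended most often for genes near the threshold, and Lpin2, Idh2 and Shmt2 lost theirs after either scaling. Depth limits what can be said of Ucp1, Dio2, Wnt1, Wnt6 and Wnt10a, which had at most 10 reads in any library.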

Other observations

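The comparisons with the share of cells, the scaling tests, the peroxisomal and cytosolic ribosomal lists and the genes that differed between replicate numbers were chosen after the results they bear on were seen; the tests of length and GC content, of mitochondrial ribosomal genes, of on and off genes and of other splits were set before theirs, though the mitochondrial ribosomal list was added after other results were known.

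Peroxisomal fatty acid oxidation genes were lower like the mitochondrial ones. Their list includes Acaa1b and was written after the large fall of that gene had been seen. After median-of-ratios scaling 18 of 21 fell and 0 rose, with a median log2 fold change of -0.55 (unscaled 16 fell and 1 rose, median -0.40, unadjusted camera p = 0.0191 with an estimated correlation). Ehhadh, the peroxisomal bifunctional enzyme, went from 101 ± 1.03 to 51.8 ± 4.04 RPKM, 1.95-fold lower. Mitochondrial ribosomal protein genes fell in 71 of 78 cases and rose in 1 after scaling, with a median of -0.37 (unscaled 62 fell and 5 rose, median -0.22, unadjusted camera p = 0.0172 with an estimated correlation). Cytosolic ribosomal protein genes went the other way: 73 of 77 were higher with a median of 0.29, and 50 were higher with a median of 0.14 after scaling (camera p = 0.191 with an estimated correlation).

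Genes differed between replicate numbers whatever the treatment, a few of them strongly. Pmp2, a fatty acid binding protein of myelin, was at 74.3 RPKM in DMSO replicate 1 and 45.2 in 611 replicate 1, and between 0.681 and 1.67 in the other 4 libraries. Sfrp2, Igfbp5 and Vcan were highest in replicate 2 of both groups, with Igfbp5 at 4.56 in DMSO and 26.8 with 611 there. In all, 46 of 13829 genes differed between replicate numbers (limma with group and replicate number, Benjamini-Hochberg adjusted p below 0.05), and 2332 had an unadjusted p below 0.05. That is more than this threshold would give on average without any difference. Genes that vary together can raise such a count, so it does not show that the difference reached beyond the genes called. These genes were singled out after their values were seen.

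With 3 libraries against 3 there are 10 splits, so no share under 0.05 is possible. The real split gave 8209 calls, the highest of the other splits gave 0, and 1 of the 10 splits, the real one, gave as many. The 3 other splits that part all 3 pairs of replicate numbers also gave 0. Every other split put libraries of both groups on each side, so the difference between the groups entered its spread. Few calls were therefore to be had from them in advance, and their counts do not speak against chance.

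The fall of adipocyte genes may have come from fewer fat cells, each as before. Genes restricted to fat cells would then have fallen by 1 common factor, provided that all fat cells were of 1 kind. Of 88 members called lower in the adipocyte, thermogenic and lipid lists, 40 fell further than Adipoq by more than 2 standard errors of the difference. Another 10 fell less. A share of cells could then not be the whole cause if Adipoq were restricted to 1 uniform kind of fat cell. No table shows that condition, so the comparison does not exclude a share of cells. Removing the trend on transcript length, GC content and expression level left the adipocyte members called lower at a median of -0.63 (from -0.72, quartiles -0.95 and -0.48), which argues against that trend as the cause. The quartiles were added to this test, as a stricter requirement, after its median had been seen. What stays open is a smaller share of fat cells, or of some of them, as part or all of the cause, next to an effect of 611 within fat cells.

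The rise of progenitor and cell cycle genes may have the same source, a larger share of cells that had not become fat cells. The median log2 ratio of the 11 progenitor markers called higher exceeded that of the 36 cell cycle genes called higher by 0.28, at 1.47 against 1.19. A difference up to 0.3 had been set as fitting a common factor, but after most of these ratios had been seen, and the quartiles, 1.34 to 1.604 and 1.11 to 1.27, did not overlap. The requirement of overlap was added once the difference was known, so this test leaves the question open. Of 49 matrix, progenitor and myofibroblast genes called higher, 17 rose further than the median cell cycle gene by more than 2 standard errors and 12 rose less. No table shows cell cycle genes to be restricted to cells other than fat cells, so their median is no limit on the share, and a larger share stays open for these genes too.

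Respiratory chain genes fell by a small and even amount, which scaling or a bias by gene type might produce. Median-of-ratios scaling gave a median of -0.54, but it lowers every 611 library, so the value could only go down and does not test that cause. Removing the trend on length, GC content and level moved the median of the members called lower from -0.40 to -0.25 (quartiles -0.31 and -0.20), and 68 of 73 stayed below -0.1. Part of the fall therefore went with that trend, and the trend was not the whole of it. Mitochondrial ribosomal genes, at -0.37 after scaling, fell as well, and a common fall of mitochondrial genes, in fat cells or through a smaller share of them, is an open hypothesis.

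The share of calls that were higher was 70.1%, and 49.9% after median-of-ratios scaling, which brings the median of all genes to 0.00 and so makes a near-even split by construction. Among changes of at least 1 on the log2 scale 312 were higher and 138 lower after it. Whether the excess of higher genes over all calls is real stays open.

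Only 1 gene went from below 0.1 RPKM with DMSO to at least 1 with 611, Wfdc3, with a median of 36 reads in the 611 libraries and 2 in the DMSO ones. Only 1 went the other way, Rmrp, which had 80 reads in DMSO replicate 1 and at most 2 in any other library. The 36 reads lie above the 10 set in advance against a cause in depth, and library totals between 3.89e+07 and 4.12e+07 cannot account for the rise of this gene. The exact 95% interval of the share switching on was 1.26% to 98.7%, so 1 gene each way decides nothing about direction.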
